A study of Mus musculus with 6 samples.

How the data were processed

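RNA of the caput epididymis was measured by RNA sequencing in 6 libraries of 8-week-old mice, 3 from wild-type animals and 3 from Adgrg2 knockout (KO) animals. Per the labels' protocols, RNA was isolated with an RNeasy kit and libraries were made with a stranded Illumina mRNA kit. The submitters' processing notes name TopHat2 2.1.1 and Cufflinks 2.2.1 and the mm10 mouse genome build. The gene annotation, the strand setting of the counting, the handling of reads that match several genes and the method used to normalize between libraries are not given in the sources used here.

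The table holds 24346 genes with an NCBI gene ID and symbol. The deposited FPKM values, fragments per kilobase of transcript relative to the library's fragments, were normalized between libraries by the authors, per the file headers. The deposited normalized counts are a signal that was normalized between libraries, per the file headers, and no longer a raw count, so the planned count model was not fitted and the test for FPKM was used. In each library 98.36% to 98.71% of the normalized counts below 300 were whole multiples of a single step within 0.05 of a step. Read as 1 fragment, that step gives a depth of 16498384 to 19723835 fragments per library, which was not checked against the reads. Genes with few fragments have coarse values: for the short Mir8102, 1 fragment corresponded to 6.95 to 8.27 FPKM in the KO libraries. An exact 0 can be a failed estimate, since the ribosomal protein gene Rpl26 was listed at 0 in wild-type replicate 2 and KO replicate 2, and Tgoln2 at 0 in KO replicate 3. Such genes are described as listed at 0, with the value of each library.

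The main test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12799 in all. The test was limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with a mean-variance trend, two-sided) on log2(FPKM + 1), with genotype as the only term and Benjamini-Hochberg adjustment, at a threshold of 0.05. Every log2 change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the tables.

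In total 42 lists of genes were fixed, covering regions and cell types of the epididymis, signalling responses, gene families and other cell types that a sample could hold. Lists with at least 3 tested members, 38 in all, were compared with the other genes by limma's camera with its preset correlation of 0.01, adjusted over the lists. Beside it stand camera with a correlation estimated for each list and fry, which asks whether a list's genes move one way on balance. With an estimated correlation no list passed the threshold, and 3 had an unadjusted p under 0.05. That version of camera also uses the few residual degrees of freedom of the libraries. A threshold lost there need not reflect the correlation. Fry does not compare a list with other genes. For each list the genes past the threshold were counted after adjustment over all tested genes and adjusted over the list alone.

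Genes were named by a rule in 5 parts: Adgrg2 in every library; 11 genes of the initial segment and of ERK signalling whatever their result; the 12 largest falls and 12 largest rises among genes past the threshold whose genotypes did not overlap; for each list up to 4 members past the threshold, or with none the 2 of highest mean expression; and the 5 genes of highest mean expression in wild-type. Members that passed only when adjusted over their list alone are named where they are few, and those outside the rule were thus chosen after their values were seen, as was Sfi1. The values of some genes that the rule or these counts cover are not reported here. Coordinates are those of the mm10 build from the RefSeq gene table of GRCm38.p6, matched by NCBI gene ID for 24260 of the genes (99.65%).

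The alternatives were pseudocounts of 0.1 and 0.01, no filter, a minimum mean of 5 FPKM, rescaling by the median of ratios, quantile normalization, robust moderation, moderation without the trend, the replicate number as a block, a minimum 2-fold change and each library left out in turn. Added after the data were seen were the normalized counts as the measure, a further minimum mean of 10 normalized counts, and removal of a gene length trend from each library (lowess with a span of 0.5 on the ratio of normalized count to FPKM). Between wild-type libraries the chi-square per degree of freedom of the rounded fragment numbers was 2.92 to 4.69, above the value of 1 that repeat counts of a single library would give.

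The test was checked on simulated data with 200 of 12799 genes changed. With each gene given its own pooled spread, 144 genes were called, 7 of them wrongly; 52% of the genes changed by 1 on the log2 scale and 85% of those changed by 2 were recovered. With the spread of the wild-type libraries in both groups, all 200 changed genes were recovered beside 12 wrong calls. Both simulated groups had equal spread, libraries were drawn independently, and changed genes were taken only from better expressed ones. The check therefore does not cover the wider spread of the real KO libraries, which the test pools with that of wild-type.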

Results

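The caput epididymis, the head region of the duct in which spermatozoa mature, was profiled by RNA sequencing in 8-week-old wild-type mice and in mice labelled as Adgrg2 knockouts (KO). Adgrg2, a gene of the X chromosome, encodes an adhesion G protein-coupled receptor of the efferent ductules and epididymis. Each genotype had 3 libraries, and the comparison asks which caput transcripts differ between the genotypes. The labels do not say whether the 3 libraries of a genotype came from separate animals, so p-values measure the spread among these libraries, which may be partly technical. The normalized counts summed to 19292869, 18956139 and 19121360 in wild-type and to 19919717, 18136864 and 21455984 in the KO.

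Wild-type libraries lay close together and KO libraries did not. The median SD of a gene within the genotype was 0.067 on the log2 scale in wild-type and 0.284 in the KO, or 0.145 in the KO without replicate 3. Across genes, the mean correlation with the wild-type libraries was 0.971 for KO replicate 1, 0.96 for KO replicate 2 and 0.894 for KO replicate 3, against 0.991 to 0.992 for each wild-type library. The first principal component held 68.2% of the variance and placed KO replicate 3 at 80.1, KO replicates 1 and 2 at -4.3 and 1.8, and the wild-type libraries between -27.7 and -24.5.

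Adgrg2 itself (NCBI gene 237175, chromosome X, 160390318 to 160498076, mm10) was at 833 ± 21.9 FPKM in wild-type and 354 ± 48.5 FPKM in the KO (SD, n = 3). The wild-type libraries held 808, 850 and 841 FPKM and the KO libraries 410, 324 and 328 FPKM, so each KO library lay below each wild-type library. The 2.36-fold lower mean did not pass the threshold over all genes (limma, log2 change -1.24 ± 0.16 SE, adjusted p = 0.0579). It passed without KO replicate 1 (adjusted p = 0.0137), without KO replicate 3 (0.015), with moderation without the trend (0.035), with quantile normalization (0.047) and with the length trend removed (0.034), in a range of 0.014 to 0.45 over the alternatives. The labels do not say which part of the gene was altered, and a value for the whole gene does not show whether the remaining transcripts are intact.

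Across the transcriptome, 22 genes fell and 10 rose in the KO, and in all 32 of them the 3 KO libraries lay on one side of the 3 wild-type libraries. Among the genes that fell were Ntsr1, the neurotensin receptor, at 18.0 ± 1.14 FPKM in wild-type and 0.204, 0.032 and 0 (listed) in the KO libraries, and Dapl1, which fell 28.3-fold from 72.8 ± 3.81 to 2.57 ± 2.29 FPKM. Transcripts known from spermatids and spermatozoa were among them too: the protamine gene Prm1 fell 12.7-fold, and the acrosomal protein gene Dkkl1 fell 8.04-fold. The genes that rose included Fer1l4, a ferlin-like gene, which rose 4.25-fold from 2.40 ± 0.11 to 10.2 ± 0.31 FPKM, and Spock1, a proteoglycan gene, which rose 2.8-fold from 17.5 ± 1.35 to 49.1 ± 6.38 FPKM.

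The 12 largest falls were those of Dapl1, Ntsr1, Zap70, Prm1, Tenm4, Dkkl1, Ttyh1, Myo16, C1ql4, Oaz3, Gsg1 and Tcea3. Dapl1 (chromosome 2, 59484653 to 59505020) fell by 4.55 ± 0.41 on the log2 scale (SE, adjusted p = 0.0225), and Ntsr1 (chromosome 2, 180499976 to 180544979) by 4.14 ± 0.13 (adjusted p = 0.000449). Zap70, the kinase of T cell receptor signalling, fell 20-fold from 24.7 ± 2.32 FPKM to 2.76, 0.515 and 0.428 FPKM in the KO libraries (adjusted p = 0.0333). Tenm4, a teneurin of the cell surface, stood at 8.91 ± 0.37 FPKM in wild-type and at 0.078, 1.02 and 0.127 FPKM in the KO libraries (adjusted p = 0.0225). Ttyh1 stood at 11.9 ± 0.996 FPKM against 0.80 ± 0.38 FPKM (adjusted p = 0.00708). The unconventional myosin gene Myo16 went from 4.97 ± 0.27 FPKM to 0.134, 0.116 and a listed 0 (adjusted p = 0.00427). C1ql4 and Gsg1 were below 4 FPKM in every wild-type library, and C1ql4 was listed at 0 in KO replicates 2 and 3 and Gsg1 in KO replicate 3. Tcea3, a transcription elongation factor gene, fell 3.56-fold from 21.9 ± 1.60 to 6.14 ± 1.85 FPKM (adjusted p = 0.0447). All of the 12 except Ntsr1 lost the threshold without each of wild-type replicates 1, 2 and 3 (limma, adjusted p from 0.0772 to 0.399). Without KO replicate 2 so did Dapl1, Zap70, Prm1, C1ql4, Oaz3, Gsg1 and Tcea3 (from 0.0636 to 0.0875). For Dapl1 the range over all alternatives was 0.0015 to 0.25.

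The 10 genes that rose were Snora43, Reg3b, Mir8102, Fer1l4, Pisd-ps1, Stac2, Spock1, Pisd-ps2, Wnk4 and Eva1b. Stac2 rose 3.28-fold to 10.7 ± 1.30 FPKM (adjusted p = 0.0225), Wnk4, a kinase that regulates ion transport, rose 2.35-fold to 7.88 ± 0.77 FPKM and Eva1b rose 1.81-fold to 23.2 ± 1.10 FPKM (adjusted p = 0.0438 for each). Reg3b, a lectin with antibacterial activity, was listed at 0 in each wild-type library and held 14.7, 6.02 and 5.14 FPKM in the KO libraries, which correspond to 152, 62.5 and 53.3 normalized counts. The calls of Snora43 and Mir8102, a small nucleolar RNA and a microRNA gene, rest on a few fragments: 3, 3 and 1 in the KO libraries for Snora43, and 1 in each for Mir8102, with both listed at 0 in wild-type. Pisd-ps1 rose 3.4-fold and Pisd-ps2 2.64-fold; both are pseudogenes of Pisd, the annotated span of Pisd-ps1 overlaps that of Sfi1, and how reads were shared between such genes is not given in the sources used here, so these values are uncertain. All of the 10 except Mir8102 lost the threshold without each of wild-type replicates 1, 2 and 3 (limma, adjusted p from 0.0772 to 0.414). All except Fer1l4, Mir8102 and Spock1 did so without KO replicate 2 (from 0.065 to 0.0875). For Fer1l4 the range over all alternatives was 0.0032 to 0.11.

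**Figure D1:**
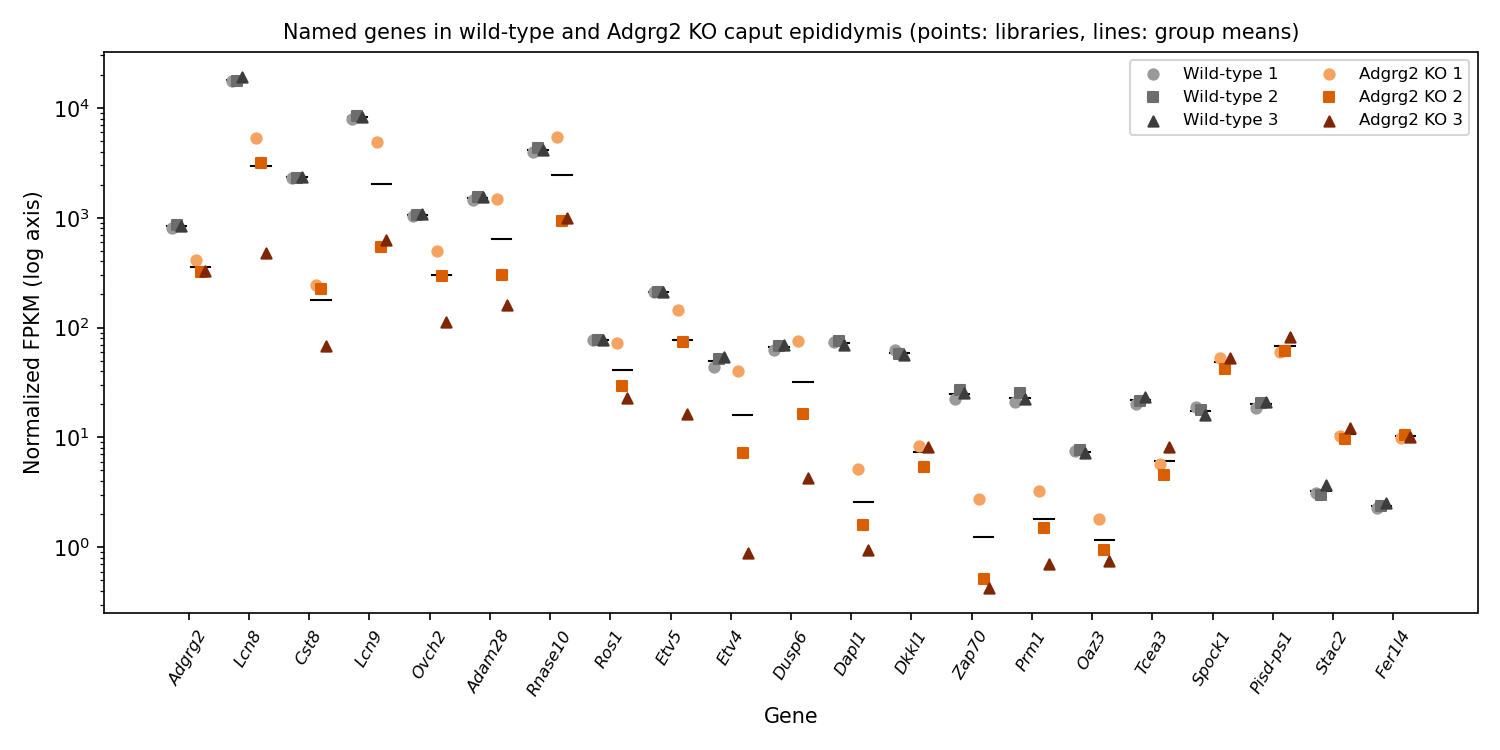
Normalized FPKM (log axis) of 21 named genes in each library of wild-type (grey) and Adgrg2 KO (orange to brown) caput epididymis, with points for libraries and lines for the group means. For Ros1 the KO libraries spread from 22.6 to 71.8 FPKM, while for Fer1l4 they sit between 9.89 and 10.5 FPKM, above all wild-type libraries.

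The count of 32 genes (limma, 12799 genes tested, adjusted p under 0.05) stands beside 2245 genes at an unadjusted p under 0.05, 17.5% of those tested. The genotypes did not overlap in 32.9% of the tested genes. Chance gives 10% only if both genotypes have the same spread. The median SD was 0.067 in wild-type and 0.284 in the KO, and such unequal spread alone raises the share. How much of the 32.9% reflects genotype is therefore not known. With a 2-fold minimum, 9 higher and 20 lower genes remained. The count depended on single libraries. It was 2 without wild-type replicate 1, without wild-type replicate 2 or without wild-type replicate 3, namely Mir8102 and Ntsr1 each time. It was 541 without KO replicate 1, 17 without KO replicate 2 and 631 without KO replicate 3, and all 32 genes were among both the 541 and the 631. These 2 fits shared 167 genes, all of the same direction, against 26.7 for independent lists, although they have 4 libraries in common, which alone raises the overlap. The test uses a single pooled spread for both genotypes. With the wider spread in the KO, p-values tend to be too small when a KO library is left out. They tend to be too large when a wild-type library is left out. This limit holds for single genes as well as for the counts.

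Germ cell transcripts were low in all KO libraries. Of the 16 tested genes in the list of spermatid and sperm transcripts, 15 had a negative change, 3 fell over all genes and 11 fell adjusted over the list alone. The list fell relative to other genes (camera, median log2 change -1.83, adjusted p = 3.03e-11), with adjusted p = 0.32 with an estimated correlation and 0.0119 by fry. Its median difference from wild-type was -1.50, -1.93 and -2.02 in KO replicates 1, 2 and 3. Prm1, which packs sperm DNA, went from 23.0 ± 2.30 to 1.81 ± 1.30 FPKM. Oaz3, an antizyme of spermatids, went from 7.43 ± 0.17 to 1.16 ± 0.56 FPKM (adjusted p = 0.0306), and Ldhc, the germ cell lactate dehydrogenase, from 2.85 ± 0.48 to 0.22 ± 0.18 FPKM (adjusted p = 0.0438). The 3 calls were lost without each of wild-type replicates 1, 2 and 3 (limma, adjusted p from 0.217 to 0.414) and without KO replicate 2 (0.0875 for Prm1, 0.074 for Oaz3 and 0.065 for Ldhc). For Prm1 the range over all alternatives was 0.0049 to 0.32. The list of Sertoli and Leydig cell markers, somatic cells of the testis, had a median of -0.21 over 6 tested genes (adjusted p = 0.852), with 0 calls over all genes by limma and 1 gene at an unadjusted p under 0.05. Its most expressed members were Sox9 at 23.0 ± 1.47 against 17.3 ± 7.80 FPKM and Inha at 7.85 ± 0.44 against 24.5 ± 13.2 FPKM, and Inha alone rose adjusted over the list alone.

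Genes of the initial segment, the first part of the caput, were low in the KO, but by very different amounts in its 3 libraries. Lcn8, a lipocalin of this segment and among the 5 most expressed wild-type genes, was at 18130 ± 846 FPKM in wild-type and at 5278, 3156 and 480.4 FPKM in KO replicates 1, 2 and 3. Cst8, a cystatin, was at 2330 ± 38.0 FPKM against 244.9, 223.1 and 68.4 FPKM. Ros1, the receptor tyrosine kinase needed for the segment to form, was at 77.4 ± 0.43 FPKM against 71.8, 29.2 and 22.6 FPKM, so KO replicate 1 was near wild-type. Adam28, a metalloprotease, was at 1525 ± 59.1 FPKM against 1468, 303.4 and 160.8 FPKM, and Rnase10, a secreted RNase A family member, at 4111 ± 174 FPKM against 5377, 926.4 and 994.7 FPKM.

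The list of initial segment genes fell relative to other genes (camera, median -1.47 over 17 tested genes, 15 of them negative, adjusted p = 6.58e-05), with adjusted p = 0.82 with an estimated correlation. No member passed the threshold over all genes with limma, 9 had an unadjusted p under 0.05, and 1, Cst8, fell adjusted over the list alone. The median was -0.29 in KO replicate 1, -1.54 in KO replicate 2 and -2.93 in KO replicate 3. Adjusted p-values over all genes were 0.0579 for Cst8, 0.162 for Ovch2, 0.183 for Lcn8, 0.206 for Lcn9, 0.26 for Ros1, 0.287 for Adam28 and 0.378 for Rnase10. Without KO replicate 1, 7 members passed, among them Ros1 (adjusted p = 0.0119, range over the alternatives 0.012 to 0.62), Adam28 (0.0193, range 0.019 to 0.62), Lcn9 (0.00488, range 0.0049 to 0.59) and Rnase10 (0.0131, range 0.013 to 0.67). Without KO replicate 3, 5 passed, among them Cst8 (adjusted p = 0.000415; also 0.026 without KO replicate 1, 0.049 with no filter on low values and 0.048 with quantile normalization, range 0.00041 to 0.41), Lcn8 (0.0209, range 0.021 to 0.57) and Ovch2 (0.0369, range 0.037 to 0.56). Fits with fewer libraries of the more variable KO tend to give p-values that are too small, so these passes are uncertain. Ggt1, a glutathione-cleaving enzyme, was at 61.9 ± 3.47 FPKM in wild-type and at 61.9, 51.3 and 134.8 FPKM in the KO, and Cst11 at 7939 ± 353 against 5690 ± 2928 FPKM.

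Targets and feedback regulators of ERK signalling were low as a list, most in KO replicate 3. Etv1, Etv4, Etv5 and Dusp6, its members with the largest falls, also belong to the initial segment list, so the results are not independent. The ERK list fell (camera, 20 tested genes, 18 negative, median -0.82, adjusted p = 0.00281), with adjusted p = 0.82 with an estimated correlation and 0.0786 without KO replicate 3 (range over the alternatives 1.1e-05 to 0.82). No member passed over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. The list median was 0.09, -0.56 and -1.90 in KO replicates 1, 2 and 3. Etv5 and Etv4 encode ETS transcription factors, and Dusp6 a phosphatase that inactivates ERK. Etv5 was at 210.0 ± 0.54 FPKM in wild-type and 143.1, 74.0 and 16.3 FPKM in the KO (adjusted p = 0.266), and Etv4 at 49.6 ± 5.39 against 40.4, 7.23 and 0.883 FPKM (0.282). Dusp6 was at 67.1 ± 3.46 against 76.1, 16.4 and 4.28 FPKM (0.345), and Phlda1 at 74.95 ± 7.41 against 74.7, 30.7 and 17.5 FPKM (0.31). In KO replicate 3, smooth muscle markers lay 3.30 and basal cell markers 2.27 log2 units below wild-type, so the library with the lowest medians of the initial segment and ERK lists was also the one with the lowest markers of these cells. The list of cAMP-induced genes had a median of 0.13 over 10 tested genes (adjusted p = 0.529), with no call over all genes by limma and 2 at an unadjusted p under 0.05. Nr4a1 was at 26.7 ± 3.004 against 32.5 ± 5.13 FPKM and Junb, which rose adjusted over the list alone, at 28.0 ± 1.79 against 49.2 ± 7.25 FPKM.

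Serine protease inhibitors and beta-defensins, families chosen by gene symbol, were higher in the KO as lists. Serine protease inhibitors rose relative to other genes (camera, 39 tested genes, 29 positive, median 0.40, adjusted p = 0.00161), with adjusted p = 0.49 with an estimated correlation and 0.0287 by fry. Beta-defensins rose as well (30 tested genes, 21 positive, median 0.67, mean 0.32, adjusted p = 0.0121), with adjusted p = 0.82 with an estimated correlation. None of their members passed over all genes with limma, while 14 and 10 had an unadjusted p under 0.05; adjusted over the list alone, 2 inhibitors (Spink10 and Wfdc18) and 3 defensins (Defb15, Defb37 and Defb6) rose. The defensin median was 0.34, 0.47 and 1.21 in KO replicates 1, 2 and 3, and the inhibitor median 0.17, 0.40 and 0.61. Examples were Wfdc10 at 3239 ± 110 against 7195 ± 3383 FPKM, Spink8 at 948.6 ± 142 against 1758 ± 952 FPKM and Defb18 at 8286 ± 583 against 8205, 13487 and 29712 FPKM. The defensin gene Defb25 was at 16370 ± 339 FPKM in wild-type against 13329, 4614 and 5102 FPKM, and the largest change of any defensin was also a fall, by 5.86 on the log2 scale. The highest defensin median was that of KO replicate 3, the library in which smooth muscle markers lay 3.30 log2 units below wild-type and luminal epithelial markers 0.81 above. With the gene length trend removed the defensin list had an adjusted p of 0.087, in a range of 0.0019 to 0.82 over the alternatives.

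The list of caput and epididymis-enriched secreted genes did not pass (26 tested genes, 16 positive, median 0.57, adjusted p = 0.0522). It shares members with the gene family lists, among them Defb15, Defb37, Spink10, Lcn6, Lcn12 and Cst12, so these results are not independent. In it 7 members rose and 3 (Crisp1, Crisp4 and Cst12) fell adjusted over the list alone, and none passed over all genes, with 12 at an unadjusted p under 0.05. It passed without wild-type replicate 1 (0.0211), without KO replicate 3 (0.0444), with a pseudocount of 0.1 (0.0497), with median of ratios scaling (0.0374), with normalized counts (0.0411) and with the length trend removed (0.0348), in a range over the alternatives of 0.0211 to 0.816. Its library medians were 0.33, 0.42 and 0.93. The most abundant transcript in wild-type was Gpx5, a secreted glutathione peroxidase, at 36160 ± 2425 against 51310 ± 6954 FPKM (adjusted p = 0.62). It took 4.72% to 5.31% of the normalized counts in wild-type and 6.3%, 6.94% and 7.35% in the KO. Spag11b, a defensin-like peptide gene, was at 19420 ± 1442 against 39770 ± 6992 FPKM (0.323) and Defb20 at 11700 ± 422 against 11740 ± 1472 FPKM (0.998). Cystatins had a median of -0.60 over 5 tested genes (adjusted p = 0.0677; 0.0496 without KO replicate 3, 0.0402 with normalized counts and 0.0291 with no filter on low values, range over the alternatives 0.0291 to 0.816). Cst8 and Cst12 fell adjusted over the list alone, with Cst12 at 4167 ± 229 against 2166 ± 460 FPKM. Lipocalins had a median of 0.08 but a mean of -0.35 over 7 tested genes (adjusted p = 0.816). Adjusted over the list alone Lcn5, Lcn6 and Lcn12 rose and Lcn8 and Lcn9 fell, and Lcn2 was at 8855 ± 131 against 9369 ± 1033 FPKM. RNase A family (median -0.08 over 9, adjusted p = 0.61) and ADAM family genes (median -0.17 over 7, adjusted p = 0.61; 0.0196 with no filter on low values, range over the alternatives 0.0196 to 0.879) did not pass. Rnase12 was at 404.8 ± 13.1 against 474.0 ± 150 FPKM and Adam7 at 4278 ± 107 against 3728 ± 957 FPKM. The list fixed as distal epididymis genes had a median of 0.20, a mean of -0.19 and an adjusted p of 0.852 over 7 tested genes. Its 2 most expressed members, given next, were abundant in the wild-type caput itself, so the list does not measure distal identity. Ly6g5c was at 3731 ± 134 against 3104 ± 2060 FPKM and Ly6g5b at 2877 ± 46.0 against 1111 ± 764 FPKM. No member of these 5 lists passed over all genes with limma. At an unadjusted p under 0.05 there were 2 cystatins, 5 lipocalins, 1 RNase, 1 ADAM gene and 2 genes of the distal list.

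**Figure D2:**
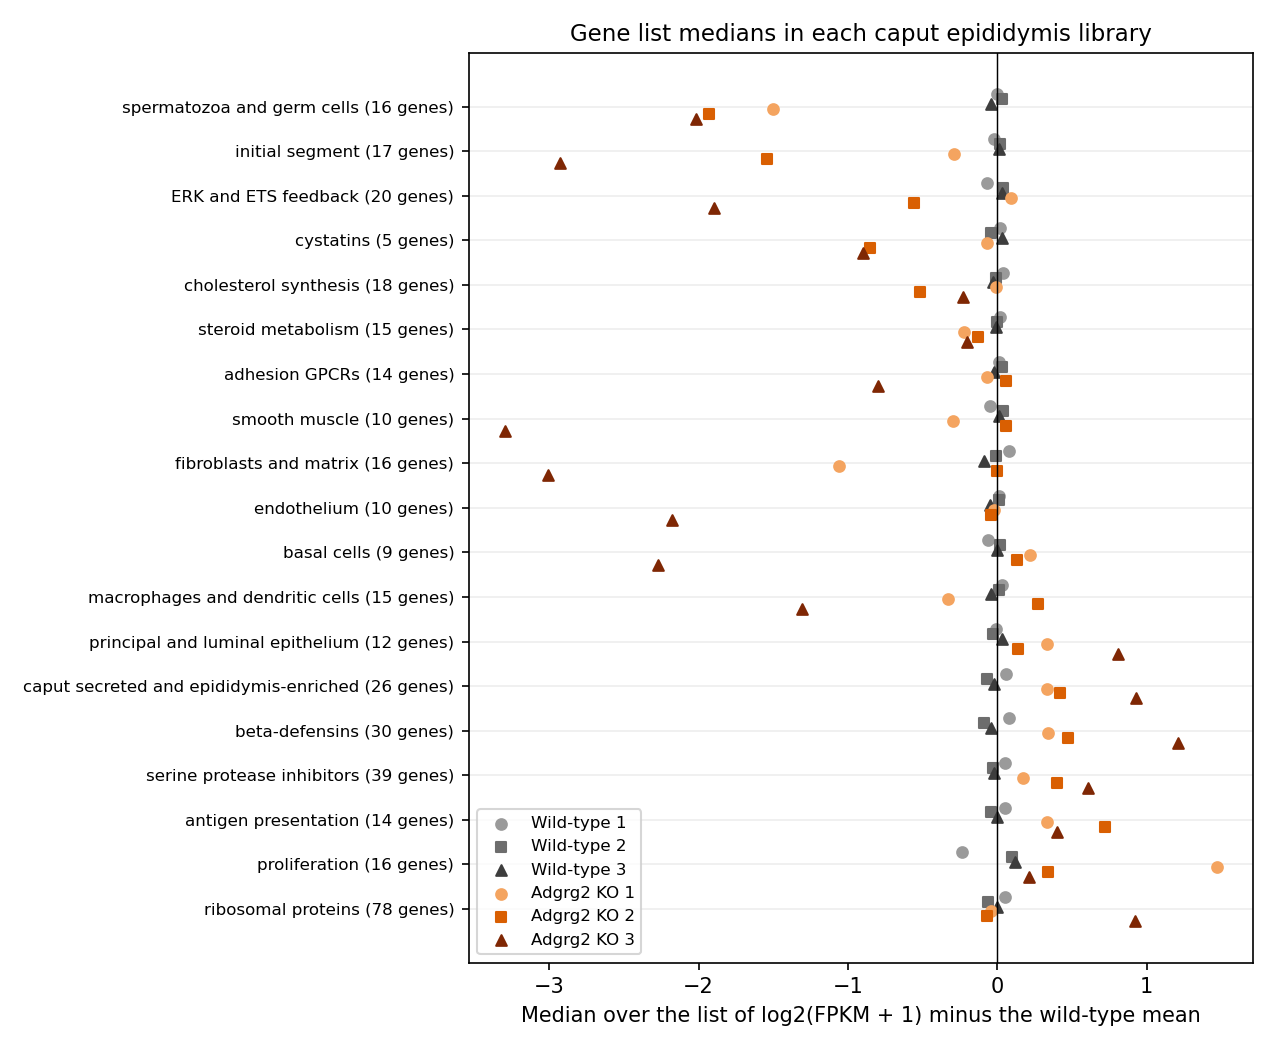
Median over each gene list of log2(FPKM + 1) minus the wild-type mean (horizontal axis), with a point for each wild-type (grey) and Adgrg2 KO (orange to brown) library. Germ cell transcripts lie between -2.02 and -1.50 in all KO libraries, whereas smooth muscle markers are at -3.30 in KO replicate 3 and at -0.30 and 0.06 in the others.

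Markers of the duct wall, connective tissue and vessels were low in KO replicate 3. The smooth muscle list had a median of -3.30 in that library, against -0.30 and 0.06 in KO replicates 1 and 2. In the same order of libraries, KO replicates 3, 1 and 2, the medians were -3.01, -1.06 and 0.00 for fibroblast and matrix genes, -2.18, -0.02 and -0.04 for endothelium, and -2.27, 0.22 and 0.13 for basal cells. Acta2, smooth muscle actin, was at 258.7 ± 11.4 FPKM in wild-type and at 192.4, 248.7 and 20.5 FPKM in the KO libraries. Sparc, a matrix protein gene, was at 319.4 ± 10.3 against 226.7, 281.3 and 11.9 FPKM, and the basal keratin gene Krt5 at 46.4 ± 1.90 against 51.2, 71.3 and 7.34 FPKM. Actg2, another muscle actin gene, was at 1828 ± 132 against 2018, 305.7 and 175.6 FPKM, and the proteoglycan gene Dcn at 196.8 ± 18.4 against 55.2, 156.9 and 15.8 FPKM. Among vascular genes Emcn was at 17.9 ± 1.65 against 18.2, 10.2 and 0.229 FPKM and Egfl7 at 41.0 ± 0.60 against 42.1, 33.6 and 30.8 FPKM.

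Smooth muscle (camera, 10 tested genes, median -1.15, adjusted p = 0.0202), fibroblast (16, -1.47, 0.00572) and endothelium lists (10, -0.87, 0.0193) fell relative to other genes, each with adjusted p = 0.82 with an estimated correlation. Without KO replicate 3 the adjusted p was 0.301, 0.0876 and 0.413, in ranges over the alternatives that reach from 0.0031, 2.2e-05 and 0.005 to 0.82. With the gene length trend removed it was 0.057 for smooth muscle and 0.05 for endothelium, and with a minimum of 5 FPKM it was 0.061 for endothelium. Basal cell markers did not pass (9 tested genes, all negative, median -0.57, adjusted p = 0.111), except without KO replicate 2 (0.0288, range over the alternatives 0.0288 to 0.824). No member of these lists passed over all genes with limma. At an unadjusted p under 0.05 there were 4 fibroblast genes and 0 in the other lists. Timp1, an inhibitor of matrix proteases in the fibroblast list, rose adjusted over the list alone, with 158.7, 65.3 and 355.9 FPKM in the KO libraries against 9.65 ± 1.33 FPKM.

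Other cell types were also read through fixed lists. Macrophage and dendritic cell genes had a median of -0.50 over 15 tested genes (camera, adjusted p = 0.0677; 4.51e-05 without KO replicate 2, range over the alternatives 4.51e-05 to 0.824) and library medians of -0.33, 0.27 and -1.31. Lyz2 was at 54.8 ± 2.94 against 31.9, 91.7 and 11.1 FPKM and Ctss at 48.9 ± 2.27 against 33.8, 58.2 and 17.8 FPKM. Luminal epithelial markers had a median of 0.46 over 12 tested genes (adjusted p = 0.0669; 0.0241 without KO replicate 2, 0.0328 with no filter on low values, 0.0496 with median of ratios scaling, 0.045 with normalized counts and 0.0185 with the length trend removed, range over the alternatives 0.0185 to 0.816) and library medians of 0.33, 0.14 and 0.81. Adjusted over the list alone Pax2 rose and Cldn10, a claudin, fell from 160.5 ± 7.37 to 28.7 ± 20.3 FPKM. Krt18 was at 314.8 ± 13.1 against 456.7 ± 151 FPKM and Epcam at 206.8 ± 10.1 against 295.7 ± 61.6 FPKM. Over all genes no member of these lists passed with limma, and 7 luminal and 0 macrophage genes had an unadjusted p under 0.05. Adhesion GPCR genes fell (14 tested, 10 negative, median -0.25, adjusted p = 0.0359), with adjusted p = 0.82 with an estimated correlation and 0.55 without KO replicate 3; the list median was -0.80 in that library, against -0.07 and 0.06 in KO replicates 1 and 2. Adgrg2 is itself in this list, and it and Adgrl3 fell adjusted over the list alone, while Adgrg1 was at 115.6 ± 1.04 against 153.5 ± 32.2 FPKM. The list also missed the threshold without a filter (0.2), with a minimum of 5 FPKM (0.13), with quantile normalization (0.088) and with the length trend removed (0.21), in a range over the alternatives of 0.005 to 0.82.

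KO replicate 3 also differed by gene length. The ratio of normalized count to FPKM, which grows with transcript length, correlated with its difference from wild-type across genes (Spearman's rho -0.41; genes are not independent replicates), against -0.10 in KO replicate 1 and 0.05 in KO replicate 2. Of 10 equal groups of genes ordered by that ratio, the lowest had a median of 0.66 in KO replicate 3 and the highest -0.36. Ribosomal protein genes, which are short, rose as a list (camera, 78 tested genes, 72 positive, median 0.27, adjusted p = 0.00672), with adjusted p = 0.88 with an estimated correlation. Their median was -0.04, -0.07 and 0.92 in the KO libraries, the last being the library with low stromal markers. Without KO replicate 3 the direction was downward (adjusted p = 0.126, median -0.07), and the rise was lost with quantile normalization (0.29) and with the length trend removed (0.58; range over the alternatives 0.00016 to 0.88). Rpl41 was at 3455, 2971 and 7229 FPKM in the KO against 3288 ± 50.7 in wild-type, and Rps26 at 2371, 2785 and 5758 FPKM against 2469 ± 73.1. None of the 78 genes passed over all genes or adjusted over the list alone with limma, and none had an unadjusted p under 0.05.

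**Figure D3:**
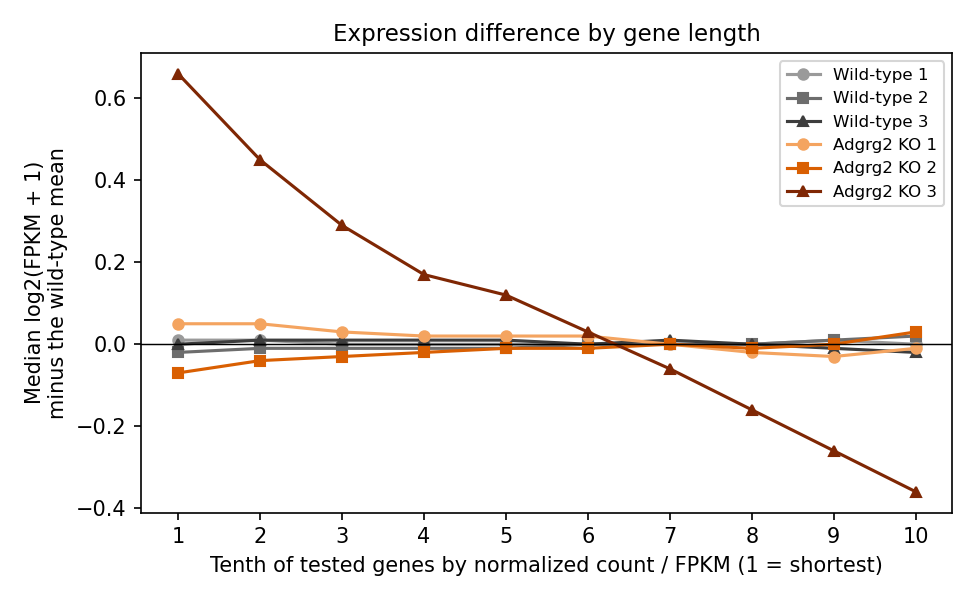
Median difference in log2(FPKM + 1) from the wild-type mean (vertical axis) for 10 equal groups of the tested genes ordered by the ratio of normalized count to FPKM, a measure of transcript length (horizontal axis), with a line for each library. The line of KO replicate 3 slopes steeply, from 0.66 to -0.36, while the other 5 stay between -0.07 and 0.05.

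Antigen presentation genes were higher in the KO as a list, but most of its class II pathway genes were not. The list rose (camera, 14 tested genes, 10 positive, median 0.48, adjusted p = 0.00165), with adjusted p = 0.32 with an estimated correlation and 0.0287 by fry, and its library medians were 0.33, 0.72 and 0.40. No member passed over all genes with limma, 8 had an unadjusted p under 0.05 and 7 rose adjusted over the list alone, among them the class I gene H2-K1, the peptide transporter gene Tap1 and the immunoproteasome gene Psmb8. The MHC class I gene H2-D1 was at 139.5 ± 4.42 FPKM in wild-type and at 406.1, 375.1 and 280.7 FPKM in the KO (adjusted p = 0.0579; 0.03 without KO replicate 1, 0.0037 without KO replicate 3 and 0.043 with no filter on low values, range over the alternatives 0.0037 to 0.44). B2m, the light chain of class I molecules, was at 1250 ± 53.4 against 2134 ± 556 FPKM (0.229). Among class II pathway genes, Cd74, H2-Eb1, H2-DMa and H2-Ab1 had log2 changes of -0.341, -0.086, -0.045 and -0.019. H2-Aa (0.126) and H2-DMb1 (0.745) had positive changes. Without KO replicate 2 the list had an adjusted p of 0.086, in a range of 2.3e-05 to 0.32 over the alternatives. The MHC genes are close paralogs that differ between mouse strains, so reads can be assigned unevenly among them. The interferon response list did not pass (17 tested genes, median 0.15, adjusted p = 0.422), except without KO replicate 3 (0.00102, range over the alternatives 0.00102 to 0.999). In it Irf9 was at 17.1 ± 0.44 against 37.0 ± 11.8 FPKM and Bst2 at 19.98 ± 0.97 against 23.1 ± 6.43 FPKM. Cytokine and acute-phase genes did not pass (8 tested, median 0.03, adjusted p = 0.819), and Nfkbia was at 26.4 ± 2.04 against 38.7 ± 6.56 FPKM. Over all genes none of the interferon and cytokine genes passed with limma, and 4 and 1 had an unadjusted p under 0.05. Lymphocyte and neutrophil lists had 1 tested gene each: Cd2 at 0.868 ± 0.12 against 1.31 ± 0.31 FPKM, and S100a8. The latter was listed at 0 in wild-type replicates 1 and 2 and KO replicate 3, and stood at 0.294 FPKM in wild-type replicate 3 and 1.53 and 4.33 FPKM in KO replicates 1 and 2.

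Cell cycle genes rose (camera, 16 tested genes, all positive, median 0.57, adjusted p = 0.00112), with adjusted p = 0.82 with an estimated correlation. The library medians were 1.47, 0.34 and 0.21 in KO replicates 1, 2 and 3, and without KO replicate 1 the adjusted p was 0.0616 (range over the alternatives 6.1e-05 to 0.82). None passed over all genes with limma, 3 had an unadjusted p under 0.05 and 1, Mcm2, rose adjusted over the list alone. Pcna was at 62.3 ± 1.67 against 78.6 ± 16.3 FPKM and Mcm2 at 9.30 ± 0.76 against 14.4 ± 1.49 FPKM. Cholesterol synthesis genes fell (18 tested, 14 negative, median -0.24, adjusted p = 0.00615), with adjusted p = 0.82 with an estimated correlation and 0.135 without KO replicate 2, whose median was -0.52 (range over the alternatives 0.00095 to 0.82). None passed over all genes, 7 had an unadjusted p under 0.05 and 4 fell adjusted over the list alone, among them Dhcr7, Lss and Insig1. The most expressed members, Fdps at 193.6 ± 2.25 against 275.2 ± 94.8 FPKM and Nsdhl at 153.6 ± 3.24 against 206.9 ± 29.1 FPKM, had higher KO means. Steroid metabolism genes fell by little (15 tested, 11 negative, median -0.18, adjusted p = 0.0371), with adjusted p = 0.55 with an estimated correlation, 0.0287 by fry, 0.172 without KO replicate 1 and 0.12 with no filter on low values (range over the alternatives 0.015 to 0.55). None passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The 5α-reductase gene Srd5a2 was at 215.3 ± 3.57 against 199.3 ± 82.0 FPKM and Hsd17b4 at 46.2 ± 1.20 against 39.4 ± 4.26 FPKM.

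The other lists did not pass. The adjusted p was 0.451 for androgen response genes (median -0.16 over 16), 0.852 for fluid and ion transport (median 0.04, mean -0.21, over 21), 0.111 for narrow and clear cells (0.39 over 9). It was 0.852 for efferent ductules (median 0.16, mean -0.14, over 14) and 0.139 for multiciliated cells (0.24 over 11). It was 0.877 for adipocytes (0.23 over 3), 0.214 for unfolded protein and integrated stress response (0.24 over 19), 0.529 for antioxidant and glutathione genes (0.05 over 27). It was 0.149 for apoptosis and p53 (0.17 over 16), 0.905 for tight junctions (-0.06 over 21) and 0.261 for solute carriers (-0.07 over 198). Of these, narrow and clear cells (0.0224, range over the alternatives 0.0224 to 0.818) and the unfolded protein list (7.23e-05, range 7.23e-05 to 0.876) passed without KO replicate 2, and multiciliated cells without KO replicate 1 (0.0317) and with no filter on low values (0.0291, range 0.0291 to 0.845).

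Apart from a single solute carrier no member of these lists passed over all genes with limma. At an unadjusted p under 0.05 there were 7 androgen response, 8 fluid and ion transport, 5 narrow and clear cell, 4 efferent ductule, 0 multiciliated and 0 adipocyte genes. There were also 1 unfolded protein, 6 antioxidant, 2 apoptosis, 5 tight junction and 51 solute carrier genes. Some members passed adjusted over the list alone. In fluid and ion transport Cftr, the chloride channel of cystic fibrosis, fell from 17.1 ± 0.24 to 6.09 ± 2.49 FPKM, while Car12, Clcn2 and Slc9a2 rose; over all genes the adjusted p of Cftr was 0.106 (limma). In the apoptosis list Cdkn1a and Pmaip1 rose, in tight junctions Cldn10 fell, and in efferent ductules Adgrg2 fell. Among solute carriers 1 gene passed over all genes, the GABA transporter gene Slc6a13, which fell from 3.80 ± 0.60 to 0.71 ± 0.24 FPKM (adjusted p = 0.0458). Its adjusted p was 0.0718 without KO replicate 2 and 0.313 to 0.391 without each of wild-type replicates 1, 2 and 3 (range over the alternatives 0.021 to 0.39). Slc6a13, Slc19a1 and Slc41a3 fell adjusted over the list alone. Atp1b1, a sodium pump subunit gene, was at 146.4 ± 3.65 against 167.2 ± 13.9 FPKM. Foxi1, a transcription factor of V-ATPase-rich cells, was at 29.7 ± 1.60 against 59.2 ± 26.3 FPKM and the ammonium transporter gene Rhbg at 37.4 ± 1.89 against 38.6 ± 8.93 FPKM. The cilia genes Ccno and Rsph1 were at 61.3 ± 3.06 against 90.6 ± 40.2 FPKM and at 10.8 ± 1.01 against 14.2 ± 8.21 FPKM. The chaperone genes Hspa5 and Hsp90b1 were at 1029 ± 19.1 against 1066 ± 366 FPKM and at 1061 ± 20 against 1405 ± 565 FPKM. Gstm2 was at 730.4 ± 36.2 against 1130 ± 345 FPKM, Bax at 54.1 ± 3.71 against 62.5 ± 19.04 FPKM and Ccng1 at 33.2 ± 0.53 against 29.5 ± 2.07 FPKM. The claudin genes Cldn2 and Cldn3 were at 424.1 ± 6.87 against 393.1 ± 15.4 FPKM and at 188.5 ± 1.99 against 286.1 ± 117 FPKM. Erythrocyte transcripts had 2 tested genes and no list test. Hba-a1 was at 75.4 ± 6.25 FPKM in wild-type and 4.88, 17.3 and 4.67 FPKM in the KO (adjusted p = 0.0772). It passed without KO replicate 2 (0.00449), with quantile normalization (0.049) and without KO replicate 3 (0.0412, range over the alternatives 0.0045 to 0.47), and it fell adjusted over the list alone. Hbb-bs was at 13.2 FPKM in wild-type replicate 3 and at 0.003 FPKM in each other library. Hba-a1 was at 77.2 and 80.6 FPKM in wild-type replicates 1 and 2, so the globin genes disagree there. Their values are therefore uncertain, and how reads were assigned among globin genes was not tested. The fat cell genes Fabp4 and Car3 were at 1.86, 20.8 and 0.159 FPKM and at 0.616, 11.5 and a listed 0 FPKM in the KO, against 2.47 ± 2.32 and 1.87 ± 2.36 FPKM in wild-type. The list of mitochondrially encoded genes had no member in the table.

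Of the 38 lists tested by camera with the preset correlation, 5 rose and 9 fell. None passed with an estimated correlation, the lowest adjusted p being 0.32 with 3 lists at an unadjusted p under 0.05, and 4 passed by fry: germ cell transcripts, serine protease inhibitors, steroid metabolism and antigen presentation. With the estimate, antigen presentation and steroid metabolism lost the threshold although their correlations, -0.02 and -0.05, lay below the preset 0.01. A higher correlation is thus not the reason for these lists. Without KO replicate 3, 5 lists were lower with the preset correlation.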

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

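The normalized counts as measure, the minimum of 10 normalized counts and the removed length trend were chosen after the data were seen; the other alternatives were planned. The main counts were 10 genes higher and 22 lower in the KO, and 5 lists higher and 9 lower. Lower genes numbered 7 with a pseudocount of 0.1, 3 with 0.01, 86 without a filter and 10 with a minimum of 5 FPKM, where 9169 genes were tested. Quantile normalization gave 40 higher and 66 lower genes, 29 of the 32 among them, and the normalized counts as measure 4 and 2. With each library left out in turn, higher genes ranged from 1 to 332 and lower genes from 1 to 352, with 5 to 7 lists higher and 5 to 10 lower. Leaving out a library leaves fewer samples and moves the pooled spread toward that of the other genotype. Beyond that the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, and by fry 2 and 2. The ribosomal protein list turned from higher to lower without KO replicate 3 (adjusted p = 0.13), in a range of 0.00016 to 0.13 over the libraries left out. Robust moderation and median of ratios scaling gave 10 and 22 genes, moderation without the trend 10 and 26, the minimum of 10 normalized counts 8 and 21, and removal of the length trend 10 and 15.

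The replicate numbers do not pair the samples: same-numbered libraries deviated from their group means with correlations of -0.113, 0.032 and 0.08 across genes, and only replicate 3 correlated best with its own number. With the number as a replicate block, limma called 0 higher and 1 lower gene, against 1821 genes at an unadjusted p under 0.05, and lists numbered 5 higher and 10 lower.

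Of the 24 named genes past the threshold, all kept their direction under each alternative that still tested them; 22 lost the threshold without each wild-type library in turn, 16 without KO replicate 2, 19 with the normalized counts as measure, 16 with a pseudocount of 0.01, 12 with 0.1 and 11 with the length trend removed. Of the named genes not past it, 12 passed without KO replicate 1 and 11 without KO replicate 3. The count tests planned in case of raw counts were not run, since the values are not raw counts.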

Other observations

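Of the tests below, those of the length trend, of the further cell type markers and of the splits were set before their results were seen; those of the basal cell markers, of a wrong label, of more initial segment tissue, of the MHC region, of an interferon response, of the level of H2-Ea-ps in KO replicate 3 and of the genes near Adgrg2 were chosen after, as were the genes named here outside the rule.

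Further caput transcripts also differed widely among the KO libraries, though not all in the order seen in initial segment genes. The defensin gene Defb48, whose fall was the largest change of the beta-defensin list, was at 8970 ± 178 FPKM in wild-type and at 2197, 11.1 and 138.1 FPKM in KO replicates 1, 2 and 3 (limma, adjusted p = 0.197). Teddm2 was at 1722 ± 206 against 922.0, 13.4 and 15.8 FPKM (adjusted p = 0.224). Krt23 was at 64.1 ± 3.54 against 33.7, 2.77 and 0.992 FPKM (0.201). Enpp2, which makes lysophosphatidic acid, was at 219.5 ± 3.64 against 158.9, 30.2 and 16.6 FPKM (0.226), and the prolyl hydroxylase gene P4ha2 at 78.3 ± 2.30 against 39.7, 4.39 and 3.63 FPKM (0.178). In the other direction, Lrg1, a secreted glycoprotein gene, was at 32.9 ± 3.27 against 78.9, 154.7 and 173.2 FPKM (0.0854). The protease gene Mmp7 was at 50.3 ± 3.40 against 142.8, 175.9 and 77.6 FPKM (0.148). For each of these genes the 3 KO libraries lay on one side of the wild-type libraries, as in 32.9% of all tested genes. None of the genes named here passed the threshold over all genes.

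Phka2 (chromosome X, 160501904 to 160598879), whose annotated span starts beyond the end of Adgrg2, was at 4.41 ± 0.27 FPKM in wild-type and at 11.2, 9.44 and 8.60 FPKM in the KO libraries (adjusted p = 0.0579). Of the 70 other tested genes whose start lies within 10 Mb of that of Adgrg2, 0 passed with limma over all 6 libraries. An unadjusted p under 0.05 was found for 21 of them, 30.0% against 17.4% of genes elsewhere (Fisher's exact test, odds ratio 2.03, 95% interval 1.15 to 3.46; neighbouring genes are not independent). Without KO replicate 3, 5 passed, 7.14% against 4.91% elsewhere (odds ratio 1.49, 0.466 to 3.68). Sfi1, whose span overlaps that of Pisd-ps1 on chromosome 11, was at 9.98 ± 0.33 against 28.4, 44.9 and 59.5 FPKM (0.059).

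The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 32 genes, and the highest of the others gave 1 gene. Each other split puts wild-type and KO libraries in the same group, so any genotype difference widens its spread and few calls are likely. The contrast therefore cannot decide the question.

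Low stromal, vascular and basal markers in KO replicate 3 were weighed against a technical trend and the make-up of the sample. The length trend of that library does not account for them: with it removed, the median of the 45 members in KO replicate 3 was -2.72 (quartiles -3.41 and -1.85), against -2.60 before. A lower share of tissue around the luminal epithelium may be part of it, as 16 markers of 4 further cell types, fixed before they were looked at, had a median of -1.25 with 12 below 0. Pericyte markers (-1.27 over 8) and lymphatic markers (-1.55 over 3) were low, but mesothelium markers (-0.02 over 3) and 2 Schwann cell markers (1.13) were not. Basal cells lie inside the duct epithelium, so a loss of tissue around the duct would not by itself lower their markers. Their median was -2.27 (9 markers, upper quartile -1.4). That value rests on 1 library and on markers that move together (estimated correlation 0.97), and it was known when the test was chosen. How the tissue was dissected and whether Adgrg2 loss changes these cells were not tested.

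Initial segment genes near wild-type in KO replicate 1 are the second pattern, which did not hold for every member. The list median there was -0.29, but Cst8, Lcn8 and Ovch2 had log2 differences from wild-type of -3.24, -1.78 and -1.09. A wrong label is argued against by Adgrg2 itself, which in that library stood at 49.2% of the wild-type mean, beyond the range of the wild-type libraries and near the other KO libraries. More initial segment tissue in that sample than in the other KO samples cannot be told apart from a milder response: it would give genes found only in that segment a single ratio between KO libraries, and the log2 ratios of KO replicate 1 to KO replicate 2 over the 17 members had a median of 0.95 and an interquartile range of 1.95. Ratios ran from 0.654 for Penk and 1.1 for Cst8 to 9.1 for Lcn9, but genes also expressed outside the segment would have smaller ratios, and how restricted each gene is was not measured. Variation between animals in the response to Adgrg2 loss stays open as well, as untested.

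MHC genes on chromosome 17 differed in a way that may reflect strain background: H2-Ea-ps (34341952 to 34344645), a class II pseudogene whose expression depends on the MHC haplotype, was at 19.9 ± 0.70 FPKM in wild-type, listed at 0 in KO replicates 1 and 2 and at 9.49 FPKM, 47.8% of wild-type, in KO replicate 3; H2-Ab1, H2-Aa, H2-Eb1, Cd74, H2-DMa and H2-DMb1 ranged from 54.2% to 107.8% there, and a depth or length effect on that level is left open. H2-K1 and H2-D1 were at 288.1% and 291.1% of wild-type in KO replicate 1, 271.0% and 268.9% in KO replicate 2 and 187.8% and 201.2% in KO replicate 3, while Glo1 (30592861 to 30612659), outside the 5 Mb stretch tested below, was at 56.3%, 56.2% and 119.5%. Interferon induces MHC genes, so it is argued against for Gm11127, which stood at 9.1% and 9.9% of wild-type in KO replicates 1 and 2 (0.664 and 0.721 FPKM, against 7.28 ± 1.11 FPKM). For H2-Ea-ps it is argued against only if the listed 0 values are real, since an exact 0 can be a failed estimate. Uneven assignment of reads among MHC paralogs was not tested for either gene. For the rise of H2-K1 and H2-D1 alone an interferon response cannot be told apart, as 17 interferon-induced genes had a median log2 FPKM ratio of KO replicates 1 and 2 to wild-type of 0.41 with an SD of 0.42, against 1.48 for these genes; as a list they passed only without KO replicate 3 (camera, adjusted p = 0.00102, range over the alternatives 0.00102 to 0.999, with 3 members past the threshold), and over all libraries had an adjusted p of 0.88 with an estimated correlation. A different haplotype in KO replicates 1 and 2 remains a hypothesis: genes called without KO replicate 3 had an odds ratio of 2.19 of lying in the 5 Mb stretch that holds the MHC (Fisher's exact test, 95% interval 1.12 to 3.91), but 1.51 (0.672 to 2.99) without the 4 genes that showed the pattern (H2-Ea-ps, H2-K1, H2-D1 and Gm11127), and of 396 windows of 5 Mb across the genome 0 passed (lowest adjusted p 0.117).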
